A study of Phaeodactylum tricornutum with 10 samples.

How the data were processed

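Polyadenylated RNA of Phaeodactylum tricornutum, a marine diatom (strain CCMP632), was sequenced from 10 cultures in 5 groups of 2. The groups were full medium for 4 days (C4d) or 8 days (C8d), medium without added phosphate for 4 days (P4d) or 8 days (P8d), and 4 days without added phosphate followed by 4 days in fresh full medium (R4d). Per the labels' protocols, cultures grew at 20 °C under 100 µmol photons per square metre per second with a 12 h photoperiod. The libraries were strand-specific and were read in 100 cycles from 1 end. Libraries were run in shared wells, and which library shared a well with which is not given in the sources used here, so no comparison within wells could be made. The hour of harvest is also not given in the sources used here.

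The authors deposited read counts per gene model as 1 combined column per group, per the file headers, with no column for a single culture. The authors deposited FPKM values (fragment counts scaled for transcript length and depth) in the same layout, per the file headers. TopHat2 version 2.0.8, Cufflinks version 2.1.1 and Cuffdiff version 2.1.1 are named, with no role or order, in the submitters' processing notes. The genome build, the strand setting of the counting and the way in which the 2 cultures of a group were combined are not given in the sources used here. The counts were whole numbers the largest of them given to 6 significant digits, and their totals differed between columns, so they were treated as unscaled. The ratio of counts to FPKM followed size factors computed from the counts and not the column totals: relative to its mean over columns it was 0.701 in P4d, beside a size factor of 0.690 and a relative total of 1.09. Each value is therefore the authors' combined value of a group, with no SD and no n.

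The design fixed before the data were examined planned edgeR's quasi-likelihood test across 10 libraries. Without values per culture no such test was possible, so no p-value is given, and no difference has a replicate check. A size rule replaced the test. It was written after the column headers, the gene symbols and a few raw values had been seen and before any ratio was computed. Counts were scaled with TMM factors (edgeR version 4.0.16 in R version 4.3.3), and 10084 of the 10402 gene models passed edgeR's filter on low counts. The log2 ratio of the scaled counts of a pair of columns was computed with a prior count of 2, in Python version 3.11.15 with numpy version 2.4.6, pandas version 2.3.3 and scipy version 1.17.1. A gene was called higher or lower where its ratio was at least 2-fold. Each ratio has a 95% exact (Clopper-Pearson) interval from the share of the pair's reads, which covers counting error only, not the spread between cultures. The reads carry no molecular identifiers, so they are not all independent molecules. A count of 0 was set to a floor of 3 reads per column for bounds, which is between 0.0533 and 0.108 in TMM-scaled CPM.

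On simulated counts for the 10084 models, 94.0% of 50 genes raised by a log2 of 1.5 in P4d against C4d were recovered, and 0.455% of 9884 genes simulated at no difference reached 2-fold. For P8d against C8d the shares were 94.0% and 0.546%, and for R4d against P8d they were 98.0% and 0.334%. The intervals covered the simulated ratio for 95.4%, 95.3% and 95.5% of the genes in these comparisons. The simulated counts held counting error only and no spread between cultures. These shares therefore check the computation and are not error rates of the 2-fold rule for cultures.

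Gene symbols came from RefSeq's annotation of assembly ASM15095v2, matched on the protein number of each model. Of the models, 10181 matched a locus tag. For 9808 of these the model name also carries a chromosome, which was equal in 100% of them and in 4.17% after shuffling. A symbol was given for 610 models. Models without one are written by their protein number. No coordinates are given, since no build is named for the files. Counts of near-identical family members, such as the antenna genes Lhcf3 and Lhcf4 and the histones, are uncertain because the counting could split reads between copies.

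The genes named in the text follow a rule set beforehand, with the 2-fold size in place of an adjusted p. For the comparisons of P4d with C4d, P8d with C8d and R4d with P8d it took the 10 genes with a symbol and a mean CPM of at least 1 with the most positive and the 10 with the most negative log2 ratios, the extreme models of any kind, up to 4 members of each list with the largest absolute log2 ratio, and all phosphate-related symbols. This gave 202 genes, of which a part is named. Of 27 gene lists planned as text patterns, 8 had members, because only symbols and no product descriptions were used. A further 24 lists were drawn from the symbols before any ratio was computed. A list's position is the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean expression, which describes these columns and is not a test. PSAT, which matched the photosynthesis pattern only by its letters, was left out.

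Alternatives planned beforehand were RLE, upper-quartile and DESeq2 (version 1.42.0) scaling, other filters on low counts, and log2 of FPKM with pseudocounts of 1 and 0.1, all used here for ratios in place of the planned tests. Scaling by column totals, a 4-fold threshold, a requirement that the counting interval excludes equality, and the comparison of P8d with P4d were chosen after seeing the data. Figures were drawn with matplotlib version 3.10.9.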

Results

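The study followed the transcriptome of a diatom through a shortage and a return of phosphate. Control cultures grew in full f/2 medium without silica for 4 days (C4d) or 8 days (C8d), and depleted cultures grew in the same medium without added phosphate for 4 days (P4d) or 8 days (P8d). Resupplied cultures (R4d) were depleted for 4 days, pelleted, and grown for 4 days in fresh full medium. They started at 250000 cells per mL, against 450000 in the other groups. Each group had 2 cultures and enters here as the authors' combined value, so no difference below could be set against a spread between cultures. The intervals are 95% exact counting intervals.

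The columns held 44895052 reads in C4d, 33380518 in C8d, 43381880 in P4d, 40088475 in P8d and 37919454 in R4d. Reads were more concentrated in the depleted groups. The 10 most abundant models held 23.7% of the reads in P4d and 20.9% in P8d, against 12.0% in C4d, 12.1% in C8d and 8.70% in R4d. SMP1 was the most abundant gene in C4d (3.64% of reads) and C8d (4.84%). In P4d and P8d it was model 47667, which has no symbol, with 6.81% and 8.81%. In R4d it was the antenna gene Lhcf5 with 1.38%. SMP1 and model 47667 were singled out after their values were seen. Scaling by column totals in place of TMM moved the median log2 ratio of all genes by -0.95 for P4d against C4d, -0.84 for P8d against C8d, 0.92 for R4d against P8d, 1.07 for R4d against P4d and 0.11 for R4d against C4d. Ratios are therefore relative to the median gene and not to RNA per cell.

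The comparison of P4d with C4d gives the state after 4 days without added phosphate. SQD2, the enzyme that completes the synthesis of sulfolipid, a membrane lipid without phosphorus, was higher with a log2 ratio of 3.04 (1379 reads in C4d and 5616 in P4d). PHOD, named for an alkaline phosphatase family, was higher by 2.12 on the log2 scale. Higher at 2-fold were 7 of 12 planned heat shock genes, 13 of 26 glycolysis and gluconeogenesis genes and 13 of 31 cytoskeleton genes. Lower were 13 of 25 light-harvesting, 9 of 13 porphyrin and 10 of 23 fatty acid synthesis genes. At 2-fold, 1768 of the 10084 models were higher and 2041 lower. Under total-count scaling the split was 670 higher and 5062 lower.

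Among the other phosphate-related symbols at 4 days, SQD1, which makes the sulfolipid head group donor, was lower (log2 ratio -1.08), and PLC-delta (-0.38) and CDS1 (-0.02) lay within 2-fold. The most extreme ratios belonged to models without a symbol. Model 39432 had 228 reads in C4d and 83539 in P4d (log2 9.51), and model 49384 had 48 and 15109 (log2 9.23). Model 38531 had 2233 reads in C4d and 1 in P4d, a ratio of 1106-fold with a counting interval from 198 to 43704. Model 768 had 45995 and 128 reads (log2 -7.46).

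Of the 12 planned heat shock and chaperone genes, 7 were higher, none lower and 5 within 2-fold at 4 days (median log2 1.19, percentile 90.1). Under total-count scaling 4 of them were higher and 2 lower (median 0.23). A wider list of 19 heat shock and chaperone symbols had 7 higher and 2 lower (median 0.32, percentile 53.4, and -0.64 under total-count scaling). HSP20B had a log2 ratio of 4.99 (interval 4.96 to 5.01), HSP20C 4.40, HSP70A 3.97 and HSP20A 3.63. Of 26 glycolysis and gluconeogenesis genes, 13 were higher and 4 lower (median 0.94, percentile 97.7), with GapC4 at 5.38, the fusion gene TPI/GapC3 at 5.01, PGK (phosphoglycerate kinase) at 4.39 and GAPDH_3 at 3.84. Of 31 kinesin, myosin and cytoskeleton genes, 13 were higher and 1 lower (median 0.86, percentile 100), with actin Act2 at 3.13 and myoA4 at 3.09. Of 52 secretory and vesicle traffic genes, 14 were higher and 2 lower (median 0.60, percentile 98.8), with Sec7D at 2.58 and SybA at 2.43. The medians of these last 3 lists lay below 0 under total-count scaling, with 7 higher and 7 lower for glycolysis, 6 and 7 for the cytoskeleton and 2 and 7 for the secretory genes. The ferric reductase FRE3 (3.77) and the protein kinase MYT1 (2.97) were also higher.

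Of 25 light-harvesting antenna genes, which encode the fucoxanthin chlorophyll proteins, 13 were lower, 2 higher and 10 within 2-fold at 4 days (median -1.07, percentile 0.0). Lhcf5 had a log2 ratio of -2.90, Lhcf8 -2.78 and Lhcr11 -2.17, whereas Lhcx2 (2.23) and Lhcx4 were among the higher ones. Of 13 porphyrin and chlorophyll synthesis genes, 9 were lower and none higher (median -1.48, percentile 0.0), with chlM at -2.83, HemA at -2.57 and HemE_2 at -2.40. Of 23 fatty acid synthesis and desaturation genes, 10 were lower and 6 higher (median -0.71, percentile 2.0). The enoyl reductase FABI was at -5.05 (554 and 7 reads) and the ketoacyl reductase FABG at -3.93, but the desaturase PTD5a at 2.18. Of 15 carotenoid and isoprenoid genes, 6 were lower and 2 higher (median -0.76, percentile 1.2). Under total-count scaling 19 antenna genes were lower and 1 higher (median -2.04), 12 porphyrin genes were lower and none higher (-2.44), 14 fatty acid genes were lower and 3 higher (-1.32), and 10 carotenoid genes were lower and none higher (-1.72). Of 4 iron starvation induced proteins, ISIP1 (-2.67) and ISIP3 (-1.99) were lower, and ISIP2A (-0.20) and ISIP2B (0.85, below 0 under total-count scaling) lay within 2-fold. MSH5, a meiosis-related mismatch repair homologue (-4.48), and TYR1 (-4.15) were among the lowest genes with a symbol.

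**Figure D1:**
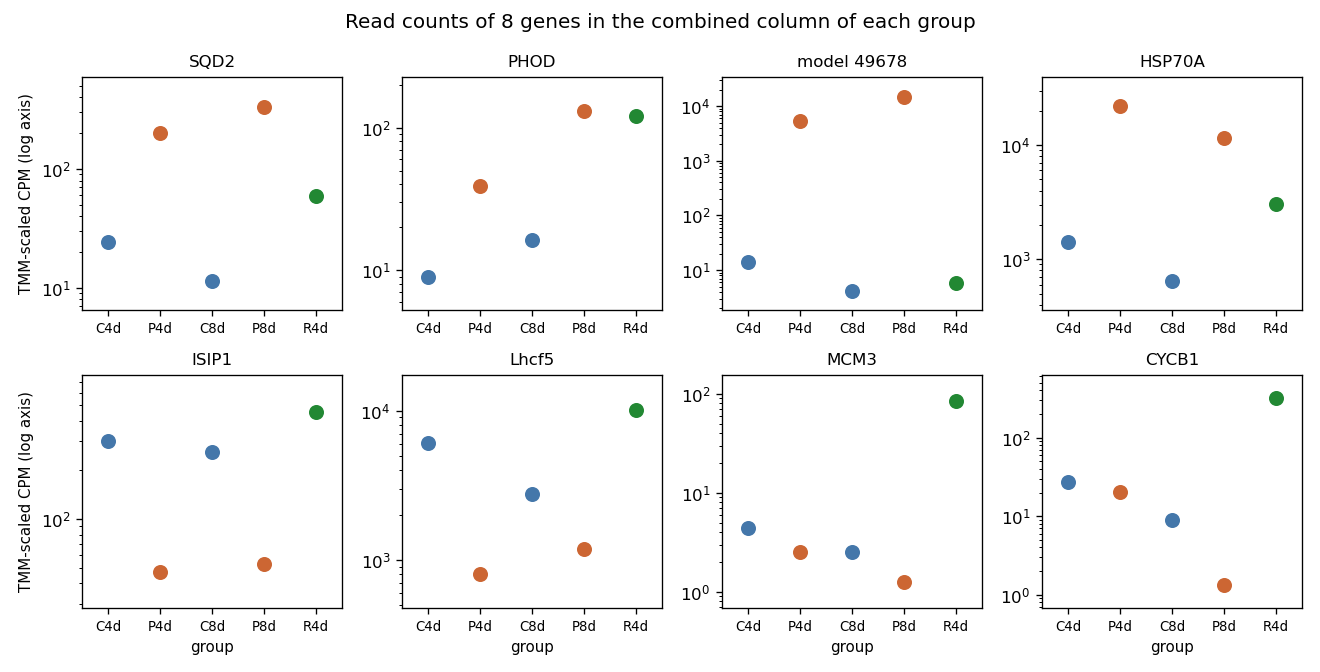
TMM-scaled CPM of 8 genes (log axis) in the combined column of each group, with controls in blue, depleted groups in orange and resupplied cultures in green. SQD2 and HSP70A lie above both controls in P4d and P8d, ISIP1 and Lhcf5 lie below them, and MCM3 and CYCB1 are highest in R4d, and points carry no error bars because each group has 1 value.

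The comparison of P8d with C8d repeats the contrast after 8 days. SQD2 was higher by 4.85 on the log2 scale (496 reads in C8d and 9497 in P8d) and PHOD by 3.01. Part of the larger SQD2 ratio lay in the control, where SQD2 was lower in C8d than in C4d (log2 -1.09). In P8d against P4d SQD2 was at 0.73, within 2-fold, and PHOD at 1.75. At 2-fold, 9 of 12 planned heat shock, 12 of 26 glycolysis and 14 of 31 cytoskeleton genes were higher. Of the 13 porphyrin synthesis genes, 9 of which were lower at 4 days, 8 were higher than in the control at 8 days, but under total-count scaling 3 were higher and 3 lower. At 2-fold, 2256 models were higher and 2435 lower. The split was 1099 and 4805 under total-count scaling, and with upper-quartile factors it was 1739 and 3140.

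At 8 days SQD1 (log2 -0.13) and CDS1 (0.14, below 0 under total-count and upper-quartile scaling) lay within 2-fold and PLC-delta was lower (-1.18). Model 49678 had 180 reads in C8d and 424080 in P8d (log2 11.78), and model 39432 had a ratio of 10.63. Model 31650 had a ratio of -8.83 and model 38531 of -7.32. Of the 12 heat shock and chaperone genes, 9 were higher and 1 lower (median 1.66, percentile 97.1), with HSP20B at 4.62, HSP70A at 4.17 and HSP20A at 3.69. Under total-count scaling 5 were higher and 2 lower (median 0.80). The wider list of 19 had 10 higher and 2 lower (median 1.17, percentile 97.4), or 5 and 4 under total-count scaling (median 0.31). Of the 26 glycolysis genes, 12 were higher and 3 lower (median 0.92, percentile 94.1; under total-count scaling 8 higher and 10 lower, median 0.06), with TPI/GapC3 at 6.04, PGK at 4.89 and the fructose bisphosphatase FBP at 4.15. Of the 31 cytoskeleton genes, 14 were higher and 5 lower (median 0.36, percentile 97.5; under total-count scaling 8 higher and 11 lower, median -0.50), with myoA4 at 4.86, myoA3 at 4.21 and Act2 at 3.90, but the kinesin Pt-KIF10 at -3.30. Of 16 genes listed from their symbols under organic acid oxidation in mitochondria, 8 were higher and 1 lower (median 1.01, percentile 97.8), with PDH1 at 3.99. Under total-count scaling 2 were higher and 3 lower (median 0.15). Where their products act in the cell was not checked. The control itself was lower in C8d than in C4d for these 16 genes (median -0.50, 5 lower and none higher). It was also lower for the 12 heat shock genes (median -0.95, 5 lower and none higher). In P8d against P4d the medians of the 2 lists were -0.33 and -0.22. FRE3 had a log2 ratio of 4.64 and MYT1 of 4.14.

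Of the 13 porphyrin genes at 8 days, 8 were higher, none lower and 5 within 2-fold (median 1.14, percentile 92.3), with HemD at 2.14, hemC at 1.89 and HemE_2 at 1.87 (list median 0.28 under total-count scaling). Over the same interval the control itself was lower for these genes, with a median of -2.81 in C8d against C4d. The 25 antenna genes had a median of 0.35 (-0.52 under total-count scaling), with 4 higher and 3 lower (2 and 7 under that scaling). Lhcx1 was at 2.31 and Lhcf8 at -1.74. The 23 fatty acid genes divided into 7 higher, 4 lower and 12 within 2-fold (median -0.05), or 4 higher and 8 lower under total-count scaling (median -0.76). Control levels of both lists were lower in C8d than in C4d, with medians of -1.29 for antenna and -1.59 for fatty acid genes. In P8d against P4d the medians were 0.07 and -0.12. ISIP3 (-2.34) and ISIP1 (-2.29) were lower, and ISIP2A (0.06) and ISIP2B (0.04), both below 0 under total-count and upper-quartile scaling, lay within 2-fold. The epimerase Rpe had 29 reads in C8d and 641 in P8d (log2 4.95), after -0.69 at 4 days. Its control level was far lower in C8d than in C4d, as given below, so the turn is no measure of induction in the depleted cultures. TYR1 (-3.14) and MSH5 (-4.47) were again low.

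**Figure D2:**
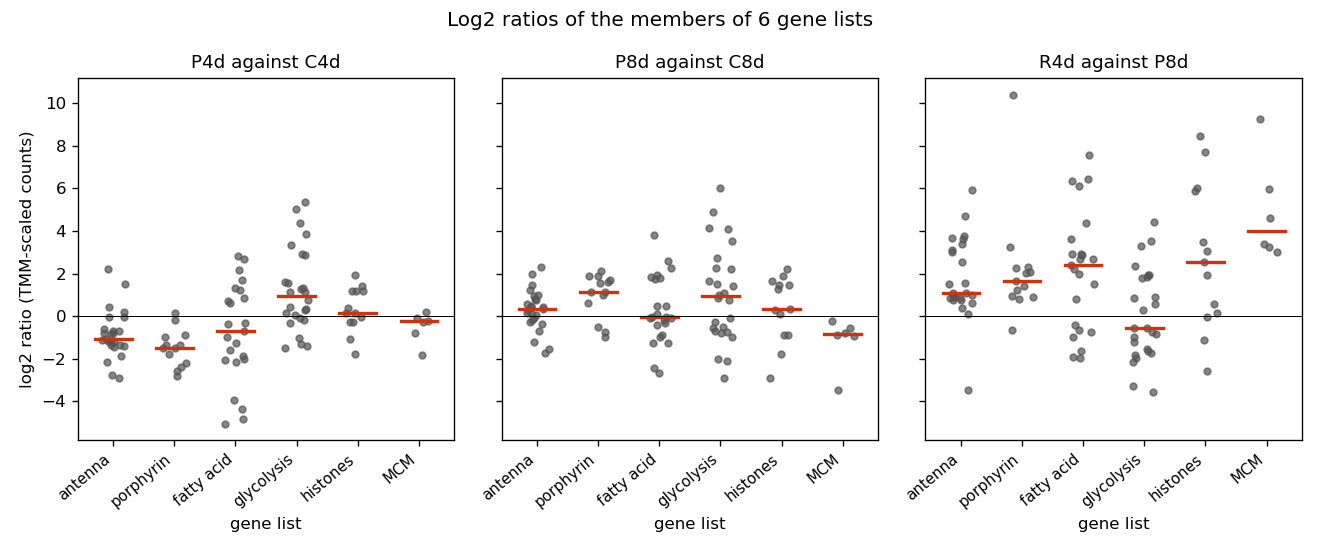
Log2 ratios of TMM-scaled counts for the members of 6 gene lists in P4d against C4d, P8d against C8d and R4d against P8d, with 1 point per gene and a red line at the list median. The porphyrin median is -1.48 at 4 days and 1.14 at 8 days, and the MCM median is 4.01 in R4d against P8d. Under total-count scaling the 8-day antenna median, the histone medians of both depletion comparisons, the 4-day glycolysis median and the glycolysis median of R4d against P8d change sign.

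The depletion ratios at 4 and 8 days share no column. Of the 1768 models higher at 4 days, 1264 were higher at 8 days, where independent lists of these sizes would share 396, and 40 were lower. Of the 2041 lower models, 1280 were lower at 8 days, where independent lists would share 493, and 66 were higher. Across the 10084 genes, which are not independent replicates, Pearson's r was 0.754 and Spearman's rho 0.697. The ratio at 8 days exceeded that at 4 days by at least 2-fold for 1655 models and was below it by as much for 1482. With upper-quartile factors these counts were 1365 and 1843. A difference between the days can lie in the controls as well as in the depleted groups. At 2-fold, 2228 models differed in C8d against C4d and 1798 in P8d against P4d.

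**Figure D3:**
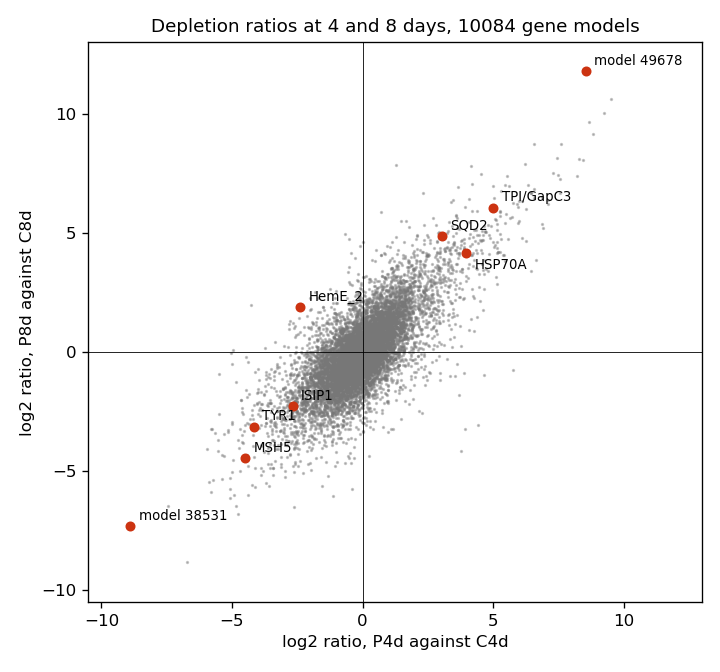
Log2 ratio of each of 10084 gene models in P4d against C4d (x axis) and in P8d against C8d (y axis), with named genes in red. Most models lie along the diagonal (Pearson's r 0.754 across genes), and HemE_2 lies in the upper left with -2.40 and 1.87.

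The comparison of R4d with P8d sets resupplied cultures against cultures kept without added phosphate. R4d also had fresh medium, a thinner inoculum and fewer days since its start. The return of phosphate cannot be told apart from these here. Between C4d and C8d, both in full medium, list medians also differed, by -1.29 for antenna, -2.81 for porphyrin and -1.59 for fatty acid genes. Higher in R4d at 2-fold were 6 of 6 MCM, 8 of 13 histone, 14 of 25 antenna, 9 of 13 porphyrin, 10 of 15 carotenoid and 15 of 23 fatty acid genes. SQD2 was lower by a log2 ratio of -2.50, while PHOD was similar in both (-0.12, and 0.82 under total-count scaling). At 2-fold, 2880 models were higher and 2269 lower. Under total-count scaling the split was 5093 and 1008, and with upper-quartile factors it was 3459 and 1783.

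All 6 MCM genes, which encode the replicative helicase, were higher in R4d than in P8d (median 4.01, percentile 100). Against the controls, 5 of the 6 lay within 2-fold and 1 was lower at each depletion day. The medians were -0.25 in P4d (percentile 56.3) and -0.83 in P8d (percentile 24.3). With total-count scaling 4 of the 6 were lower at 4 days and 6 at 8 days. MCM5 had 1555 reads in R4d and 0 in P8d. With the 0 set to the floor of 3 reads it was 287-fold higher, with a lower counting bound of 233-fold. MCM3 had a log2 ratio of 5.99. Of 13 histone genes, 8 were higher and 2 lower (median 2.53, percentile 100; 10 and 1 under total-count scaling), with H3-1b at 7.71 and H3-1c at -2.59. Against the controls, 5 histone genes were higher and 2 lower in P4d, and 6 were higher and 2 lower in P8d. With total-count scaling these became 0 and 3 in P4d, and 2 and 4 in P8d. Of 58 cyclin, cyclin-dependent kinase and cell cycle control genes, 26 were higher and 11 lower (median 0.77, percentile 99.5), or 36 and 6 under total-count scaling (median 1.70). The mitotic cyclin CYCB1 had 38 reads in P8d and 16284 in R4d (log2 7.84), CYCA/B_1 had a ratio of 7.37 and Pt-separase 6.72, but dsCYC7 one of -2.86. Diatom-specific cyclins (11 genes) had a median of 1.55, with 6 higher and 2 lower, but their position relative to the median gene turned negative with stricter filters on low values. TRD2 had 1 read in P8d and 7586 in R4d, a ratio of 4201-fold with a counting interval from 754 to 1.66e+05. Model 46513 had 0 and 9175 reads, 1694-fold higher at the floor of 3 reads, with a lower counting bound of 1377-fold.

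Of the 25 antenna genes, 14 were higher and 1 lower in R4d than in P8d (median 1.08, percentile 100), with Lhcx2 at 5.92, Lhcf16 at 4.68 and Lhcf5 at 3.09, and with Lhcx4 at -3.49. Of the 13 porphyrin genes, 9 were higher and none lower (median 1.63, percentile 100). HemF_2, a coproporphyrinogen oxidase, had 16 reads in P8d and 42485 in R4d (log2 10.40). Of the 23 fatty acid genes, 15 were higher and 3 lower (median 2.41, percentile 100), with FABI at 6.36 and FABG at 4.37. FABD had 0 reads in P8d and was 91.4-fold higher at the floor of 3 reads, with a lower counting bound of 74.0-fold. Of the 15 carotenoid genes, 10 were higher and 1 lower (median 1.84). With total-count scaling the antenna genes had 24 higher and 1 lower (median 2.01), the porphyrin genes 12 and none (2.56), the fatty acid genes 16 and 1 (3.32) and the carotenoid genes 12 and none (2.76). ISIP3 (4.06) and ISIP1 (3.12) were higher. Model 39432 (-12.08) and model 49678 (-11.31) had the lowest ratios, and GEL3 (-4.07), the aldolase Fba4 (-3.57), MYT1 (-3.32) and GAPDH_3 (-3.27) were low among genes with symbols. Of 9 ribosome biogenesis and RNA polymerase genes, 5 were lower and 2 higher (median -1.03, percentile 1.9), with BMS1 at -3.62 and RNAP-II_3 at 3.78, but 2 were lower and 2 higher under total-count scaling (median -0.13).

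Of the models higher at 4 days of depletion, 975 were lower in R4d than in P8d, where independent lists would share 398, and 279 were higher. Of those lower at 4 days, 1190 were higher in R4d than in P8d, where independent lists would share 583, and 132 were lower. These comparisons share no column. Across genes Pearson's r was -0.477 and Spearman's rho -0.462.

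The comparison of R4d with C4d sets resupplied cultures against controls that also grew for 4 days in full medium, although from a denser inoculum. At 2-fold, 1989 models were higher and 1403 lower. All 6 MCM genes were higher (median 3.81, percentile 100), as were 11 of 13 histone genes (median 3.36) and 23 of 31 cytoskeleton genes (median 1.94, percentile 100), with none of either list lower. Of the 58 cyclin, cyclin-dependent kinase and cell cycle control genes, 20 were higher, 7 lower and 31 within 2-fold (median 0.41, percentile 99.0). PHOD had 505 reads in C4d and 6247 in R4d (log2 3.76), more than the 1091 in P4d, and SQD2 had a ratio of 1.27. GapC4 (7.73), Lhcx2 (6.49), TPI/GapC3 (6.43) and PGK (5.93) were higher in R4d than in C4d, and SHMT was at 3.57. Their lists lay nearer to the control. Antenna genes had 8 higher, 0 lower and 17 within 2-fold (median 0.14). Glycolysis genes had 8 higher, 3 lower and 15 within 2-fold (median 0.27, percentile 97.6). Porphyrin genes had 2 higher, 0 lower and 11 within 2-fold (median 0.23). Model 768 (-3.63), FRE5 (-3.11) and model 38531 (-2.94) were lower. Of the 1768 models higher in P4d than in C4d, 707 were also at least 2-fold higher in R4d than in C4d, 927 lay within 2-fold and 134 were lower. Of the 2041 lower models, 497 were also lower in R4d, 1282 lay within 2-fold and 262 were higher. Independent lists of these sizes would share 349 higher and 284 lower models. Both ratios use the C4d column, from which part of the excess may come. Columns simulated with no difference and counting error only shared 6 higher and 3 lower models, which leaves out the spread between cultures.

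In R4d against P4d, the age at which phosphate was returned, 2614 models were higher and 1909 lower, and under total-count scaling the split was 5597 and 650. The 6 MCM genes had a median of 4.49, the 13 histone genes 2.97 and the 25 antenna genes 1.21, each at percentile 100 (5.54, 4.04 and 2.29 under total-count scaling).

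With age in full medium (C8d against C4d), 922 models were higher and 1306 lower. All 13 porphyrin genes had a ratio below 0 and 11 of them were lower at 2-fold (median -2.81, percentile 0.0), with hemC at -3.54 and HemE_2 at -3.44. Of the 25 antenna genes, 17 were lower and none higher (median -1.29), with Lhcx1 at -3.15 and Lhcf3 at -2.64. Of the 23 fatty acid genes, 14 were lower and none higher (median -1.59, percentile 0.0), with FABI at -4.76. GapC1 had 46309 reads in C4d and 1908 in C8d (log2 -4.21), and Rpe was at -5.43. TIM_2 (2.15), MCM4 (1.86) and ACL (1.73) were higher.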

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

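The tests of counting error, column scaling, control age and exchanged columns in this part were chosen after the results they concern had been seen, as was the bootstrap interval of the first test. The test of column scaling replaced one under total counts, which moved R4d against C4d by only 0.11 and could not decide. The tests without the abundant genes, of dsCYC2 and of the FPKM ratio were set before.

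Between the depletion ratios at 4 and 8 days, 106 models were at least 2-fold apart from their control in opposite directions, of which 66 were lower at 4 days and higher at 8 days. Of the 106 models, 10 had a symbol. Among the named genes the models were HemE_2, hemC, hemE, GluRS_2 and the triose phosphate translocator Tpt3. The log2 ratio at 8 days exceeded that at 4 days by 4.265 for HemE_2, 3.401 for hemC, 2.909 for hemE, 2.615 for GluRS_2 and 3.798 for Tpt3. Without values per culture these differences were not tested.

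Of these 5 genes, 4 belong to the 13 porphyrin and chlorophyll synthesis genes, whose depletion ratio differed between the days by a median of 2.62. The naming rule took up to 4 members of each list per comparison, so the 4 of 5 is no measure of concentration in this list. An exchange of the C8d and P8d columns is argued against by SQD2 and PHOD, of which the smaller log2 ratio in P8d against C8d was 3.01. At 8 days 8 of the 13 were higher than in C8d and none lower, but under total-count scaling 3 were higher and 3 lower (median 0.28). The difference lay in the control: C8d against C4d accounted for 106% of its sum over the 13 genes, while P8d against P4d had a median of -0.08 and left 11 of 13 within 2-fold. A single odd library in the C8d column stays open. The median FPKM ratio of C8d to C4d was -2.74, further than 1 empty library of 2 could lower an equally weighted mean, but the weights behind the columns are not given in the sources used here. A lower level of these transcripts in older control cultures may therefore underlie the turn, as a hypothesis, with culture age, density and hour of harvest not separable.

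The 6 MCM genes stood higher in R4d than in C4d as well as in P8d. Of the 58 cyclin, cyclin-dependent kinase and cell cycle control genes, 20 were higher and 7 lower than in C4d (median 0.41, percentile 99.0), with CYCB1 at 3.53 and CYCA/B_1 at 4.27. The 11 diatom-specific cyclins among them had 4 higher and 3 lower (median 0.16, percentile 59.5). Low counts in the MCM genes are argued against by their lower counting bounds, which lay above a log2 ratio of 1 in 6 of 6 genes. Scaling of the columns moves all genes alike and is argued against by their median log2 ratio, which lay 3.80 above that of all genes. The lowest of the 6 ratios was 2.13, and the medians of random lists matched on expression ran from -0.70 to 1.41 (central 95%). These values restate the list's position in this comparison (percentile 100) and add no separate support for the difference. Harvest soon after light onset would raise dsCYC2, a cyclin induced by light. Its ratio was 1.69 with a counting interval from 0.50 to 4.17, which cannot be told apart from either outcome at these counts. The thinner inoculum of R4d, another stage of growth and another hour of harvest stay open and untested.

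Under total-count scaling the median gene had a log2 ratio of -1.01 in P4d against C4d, and -0.92 in P8d against C8d. Leaving out the 100 most abundant genes of every column (231 models, with 59.8% of the reads in P4d and 41.8% in C4d) moved these medians to -0.49 and -0.57. The limit set beforehand for abundant transcripts as the main source was -0.50. The bootstrap interval of the 4-day value, -0.52 to -0.46, spans it, so that value does not decide, and the 8-day interval, -0.61 to -0.54, lies below it. The bootstrap resampled genes, which are not independent replicates, and leaves out the spread between cultures. Its intervals therefore do not measure how far the medians would vary between cultures. A stricter limit of 0.1 either side of 0, considered earlier, was met by neither median. Abundant transcripts may thus account for part of the shift, and whether most transcripts were also fewer per cell cannot be told apart without RNA per cell or a spike-in.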

How the results depend on the processing

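No paired analysis was possible because the columns carry no replicate numbers. For the same reason the DESeq2 test, the fits on only the groups compared, limma on FPKM, camera with an estimated correlation, fry, the replicate block and leaving out each culture were not run. Scaling by column totals, the 4-fold threshold and the requirement on the counting interval were chosen after seeing the data, the others before. Under total-count scaling, 5732 models were at least 2-fold different in P4d against C4d. The models shared by both depletion days became 479 higher and 3683 lower, and those reversed in R4d against P8d became 340 of the higher and 3360 of the lower, which follows from the shift of all ratios in 1 direction. A 4-fold threshold left 1297 models for P4d against C4d, 1863 for P8d against C8d, 2421 for R4d against P8d, 1280 for R4d against C4d, 1894 for R4d against P4d, 465 for C8d against C4d and 730 for the difference between days, as a stricter threshold must. For C8d against C4d, log2(FPKM + 1) gave 1433 models, and 1415 with a mean FPKM of at least 1, and the cause was not tested. Models lower in the difference between days went from 1482 to 981 with log2(FPKM + 1) and a mean FPKM of at least 1, and the cause was not tested. All other totals of models, both directions together, stayed within 1.5 times under RLE, upper-quartile and DESeq2 factors, the filters and both FPKM pseudocounts, and under the counting interval, which was run for pairwise comparisons only. RLE and DESeq2 factors were nearly the same, and the FPKM values followed a similar scaling. These 3 settings are therefore not separate checks of the scaling. For the totals of P8d against P4d only the counting interval was run, which kept 831 of 851 higher and 851 of 947 lower models. Total-count scaling moved the counts in each direction by more than 1.5 times for P4d against C4d, P8d against C8d, R4d against P8d and R4d against P4d, whose splits are in the report. Of 3156 alternatives to 353 ratios of named genes, none turned a ratio of at least 2-fold. These ratios come from P4d against C4d, P8d against C8d and R4d against P8d. There the largest shift of a median log2 ratio by any scaling was -0.95, which is short of 2-fold. A column factor could therefore not have turned such a ratio, and the absence of reversals says nothing about scaling. Of 1890 alternatives to 210 list medians relative to the median gene, 2 reversed a median outside the central 95% of random lists, both for diatom-specific cyclins in R4d against P8d: -0.27 with a CPM of at least 1 in 2 columns and -0.21 with a mean FPKM of at least 1, and the cause was not tested. A factor per column cancels in a median relative to the median gene, so the scaling alternatives could hardly reverse one. List medians not taken relative to the median gene did change sign under total-count scaling for several lists, as given above. Setting members at 0 reads to their bound moved none of the 13 list medians that hold such a member. Depth limits the ratios of genes with few reads in a column, such as MCM5, FABD and H3-1a with 0 in P8d. MCM5 and FABD are given at the floor with a lower counting bound, and the ratio of H3-1a is not given. Some other genes with few reads in a column, such as FABI, are given as plain ratios without their intervals.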

Other observations

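Sit1, a silicon transporter, had 126 reads in P8d and 9210 in R4d (log2 5.32), and 898 in C4d. Lhcx2, of an antenna family linked to photoprotection, had 113642 reads in R4d and 1382 in C4d. The desaturase-family genes PTD12 (log2 6.43 against P8d) and PTD5b (2.90) and the zinc transporter family gene ZIP1 (4.47) were also higher in R4d than in P8d.

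Several gene lists lay near the middle of the random lists in P4d against C4d. The 33 proteasome, SCF and signalosome genes had 2 higher and none lower (percentile 44.0), the 18 nitrogen assimilation genes 3 higher and 4 lower (percentile 34.4), the 14 ion transport genes 3 higher and 3 lower (percentile 45.4) and the 12 redox genes 2 higher and 2 lower (percentile 74.1). Under total-count scaling these became 1 higher and 13 lower for the proteasome list, 1 and 8 for nitrogen, 1 and 6 for ion transport and 1 and 5 for redox.

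Within a column the ratio of counts to FPKM, relative to the other columns, varied most over 8233 genes in C8d, with an SD of 0.0903 on the log2 scale, against 0.0223 in C4d, 0.0239 in P4d, 0.0316 in P8d and 0.0405 in R4d.

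The hypothesis that genes next to each other on a chromosome have similar depletion ratios was set before its test. Over 9095 adjacent pairs the correlation of log2 ratios in P4d against C4d was 0.138, and the highest of 1000 shuffles of gene order within chromosomes was 0.0331. In P8d against C8d it was 0.149 and in R4d against P8d 0.133. This is consistent with a weak similarity of neighbours, but tandem copies that share reads and overlapping transcripts were not separated.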
